A study of Drosophila melanogaster with 60 samples.

How the data were processed

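The samples were 60 RNA libraries of abdominal fat tissue left on the epidermis after the gut, ovaries and Malpighian tubules had been taken out, from mated females about 3 days old, with 10 flies per sample. Per the labels, flies were entrained for 5 days in 12 h of light and 12 h of dark, in a pair of incubators with inverse schedules, and the Clk-Jrk allele had been backcrossed for 7 generations. Poly(A) RNA was sequenced. The authors ran kallisto 0.46.2, which assigns reads to transcripts without aligning them. For each group they deposited a table of estimated counts per gene, not scaled between libraries, and a table of TPM (abundance scaled for transcript length and library total), both over 13969 genes. Of the nonzero estimated counts, 80.5% lay within 0.001 of a whole number. The transcriptome release, and how transcripts were summed to genes, are not given in the sources used here. Gene positions come from the BDGP6.54 annotation, which is a separate source.

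Total estimated counts per library ran from 4923858 to 46590109. Precision was taken from the spread between libraries, which holds counting error and more, and no share is given for a lone library. The columns of wild type at 18 °C, replicate 1, at ZT 2 and ZT 20 were identical. The design had planned all 24 libraries of that group, and the pair was left out of the main fits once it was seen, so that n = 22. Fits with both columns kept, or with the pair taken as either time, were added as alternatives.

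Samples were grouped by the labels, and the tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Estimated counts were rounded. Genes were kept by filterByExpr of edgeR over the 3 groups, which left 9348, and libraries were scaled by TMM within each fit. Tests were quasi-likelihood tests in edgeR 4.0.16 (R 4.3.3) with Benjamini-Hochberg adjusted p under 0.05. Levels were compared with a mean per group and ZT and a contrast of the group means over the shared ZT. Rhythm was tested with a cosine and a sine of a 24 h period on both terms together, and differences in rhythm with their interactions with temperature or genotype. Clk-Jrk was compared with the 12 wild-type libraries at the same times. Amplitudes, peak times and their SE come from least-squares cosine fits of log2 CPM with a prior count of 2. The amplitude is the peak minus the mean on the log2 scale.

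There were 29 gene lists, of which 8 were markers of other tissues (ovary, gut, Malpighian tubule, muscle, haemocyte, oenocyte and epidermis, neuron, spermatheca). The other lists covered the core clock, immunity, chaperones, lipid, sugar and amino acid metabolism, secreted proteins, insulin signals, antioxidants, thermal acclimation, respiration, ribosomes, proteasome, detoxification enzymes and mitochondrially encoded RNA. The 28 lists with at least 3 tested members were tested by camera in limma 3.58.1 with a preset correlation of 0.01, with camera at an estimated correlation and fry as checks. Camera asks whether a list moves against other genes, and fry whether its genes move, on balance, 1 way. Lists of rhythmic genes were compared with other genes by one-sided Fisher's exact tests. Where the text gives a value in replicate 1 or 2, it comes from a fit or a mean of that replicate alone.

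Named genes were the core clock list, up to 4 members of each other list with the smallest adjusted p, the 8 highest and 8 lowest fold changes among genes past the test with a mean log2 CPM of at least 3 and 1 sign at every shared ZT, the 12 largest amplitudes, and the 12 smallest p for differences in rhythm. Yp1 to Yp3, Hsp22, Hsp23, Hsp68, Hsc70-4, InR and pkm were named after their values were seen.

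Alternatives set beforehand were RLE size factors, DESeq2 1.42.0, no filter, a mean log2 CPM of at least 3, limma-trend on log2(TPM + 1), a replicate term, each replicate or each ZT left out, an adjusted p under 0.01, a 2-fold minimum, ZT as a factor, a 12 h harmonic, and a step between ZT 2 to 12 and ZT 14 to 24, which stands for the incubators and is inferred from the inverse schedules, as the incubator of each sample is not given in the sources used here. Alternatives chosen after seeing the data were the handling of the identical pair, a replicate term per group, the step with its interaction, marker list means as covariates, and a run without 6 libraries. Those 6 held high marker RNA of ovary (wild type at 25 °C, replicate 1, ZT 2 and ZT 4), gut (the same series, ZT 14) or photoreceptors (the same series, ZT 10, and wild type at 18 °C, replicate 1, ZT 24), or little mitochondrially encoded RNA (Clk-Jrk, replicate 2, ZT 22). Python 3.11.15 was used for tables and plots.

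The fits were tested on simulated data with the real library sizes and dispersions and 200 changed genes each. Simulated libraries were independent, without differences shared by a replicate series or RNA of other tissues. The shares below may thus be too high for the real libraries. For levels with temperature, 61.2% of log2 changes of 0.5 and 95.5% of changes of 1 were recovered, and with genotype 41.8% and 91.0%. For rhythm, amplitudes of 0.5 and 1 were recovered in 73% and 93% at 25 °C, 65% and 95% at 18 °C, 39% and 90.0% in Clk-Jrk, and 11% and 76% in the 12 wild-type libraries at the same times. For differences in rhythm the shares were 45% and 87% between temperatures and 15% and 67% between genotypes. Between temperatures the simulated difference was a fixed shift in peak time at equal amplitude, and between genotypes a full loss of rhythm in Clk-Jrk. Other shifts, changes in amplitude and partial losses were not simulated. In every fit the changed genes were drawn from those with a mean above 0.5 of the median, so genes with lower counts were not tried. False calls made up 9.1% of calls for rhythm at 18 °C, 10.9% for the difference in rhythm between genotypes and at most 6.5% in the other fits.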

Results

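RNA of abdominal fat tissue, the fly's counterpart of liver and adipose tissue, was sequenced around the 24 h day in 60 samples of mated female Drosophila melanogaster. Wild-type (w1118) flies were held at 18 °C (24 samples) or 25 °C (24 samples), and flies carrying Clk-Jrk, a mutant allele of the circadian activator gene Clock (Clk), were held at 25 °C (12 samples). Wild-type flies were sampled at 12 times, every 2 h, and Clk-Jrk flies at 6 times, every 4 h, with 2 replicates at each time. Times are zeitgeber times (ZT), the hours after lights on, and lights went off at ZT 12. Clk-Jrk flies at 18 °C were not analysed here. The total of estimated counts per library ran from 4923858 to 25133564 in wild type at 18 °C, from 5808864 to 46590109 in wild type at 25 °C, and from 10667764 to 28822277 in Clk-Jrk. The columns for wild type at 18 °C, replicate 1, at ZT 2 and at ZT 20 held identical values for all 13969 genes. Their time of day could not be told, so both were left out and the group at 18 °C had n = 22 libraries. Each level below is a log2 CPM (a count scaled to the library total), each ± after a mean is an SD over libraries, and each ± after a fitted value is an SE.

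The first question was which transcripts followed the day in wild-type flies at 25 °C (n = 24 libraries). The clock genes tim, vri, per and Pdp1 had their fitted peaks in the night there, and much of their rise came before lights off. RNA of timeless (tim, FBgn0014396), whose protein pairs with PER in the negative limb of the clock, peaked at ZT 17.3 ± 0.46 h with an amplitude of 1.51 ± 0.18 and a peak 8.16-fold over its trough (edgeR adjusted p = 0.0017). RNA of vrille (vri, FBgn0016076), a repressor of Clk, peaked at ZT 15.5 ± 0.40 h, 4.70-fold over its trough (adjusted p = 6.71e-05). RNA of period (per, FBgn0003068) peaked at ZT 15.7 ± 0.72 h, 2.69-fold over its trough, and RNA of Pdp1 (FBgn0016694), an activator of Clk, at ZT 15.8 ± 0.63 h, 2.38-fold over its trough (adjusted p = 0.0364 and 0.0109). Clk itself ran in the opposite phase, with a fitted peak at ZT 4.66 ± 0.86 h and an adjusted p of 0.114.

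Of the 15 core clock genes, 4 passed over all genes and 7 passed when adjusted over the list alone, where Clk, cwo and cry joined the first 4. The share that passed was above that of the other genes tested (one-sided Fisher's exact test, adjusted p = 7.7e-06, genes not being independent replicates). Of 22 antimicrobial peptide genes 0 passed over all genes in edgeR, and 10 passed when adjusted over the list alone (14 at an unadjusted p under 0.05). Gut and ovary markers had 3 each by the list alone, of 23 and 28. Among detoxification genes, 2 of 25 UDP-glycosyltransferases passed (5 when adjusted over the list alone), with Ugt36D1 peaking at ZT 3.37 and Ugt37D1 at ZT 13.98, and 1 of 29 glutathione S-transferases, GstZ2, which peaked at ZT 0.48. The morning genes CG17560 and CG17562 peaked at ZT 4.92 and ZT 4.84, 4.01-fold and 3.19-fold over their troughs, and geko at ZT 0.79, 3.48-fold over its trough. The gene slf peaked at ZT 15.7 and CG6409 at ZT 16.9. The chorion gene Cp7Fa, which belongs to ovarian follicle cells, peaked at ZT 2.88 ± 0.93 h with an amplitude of 2.72. It passed beside high RNA of the ovary marker list in replicate 1 at ZT 2 and ZT 4, and was the only ovary marker of 28 that did.

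Over all 9348 genes tested, 37 were rhythmic at an adjusted p under 0.05, and 834 had an unadjusted p under 0.05 where 467 would be expected by chance. Their median amplitude was 0.73, and 15 peaked between ZT 0 and ZT 6 and 11 between ZT 12 and ZT 18. The count moved with the fit: DESeq2 called 103 genes, 1 replicate alone gave 12 or 3, 16 to 37 passed with a time point left out, and 20 without the libraries that held marker RNA of other tissues. With a term for a step between ZT 2 to 12 and ZT 14 to 24, 3 genes passed. That split stands for the pair of incubators with inverse schedules and is inferred, since the labels do not name the incubator of each sample.

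**Figure D1:**
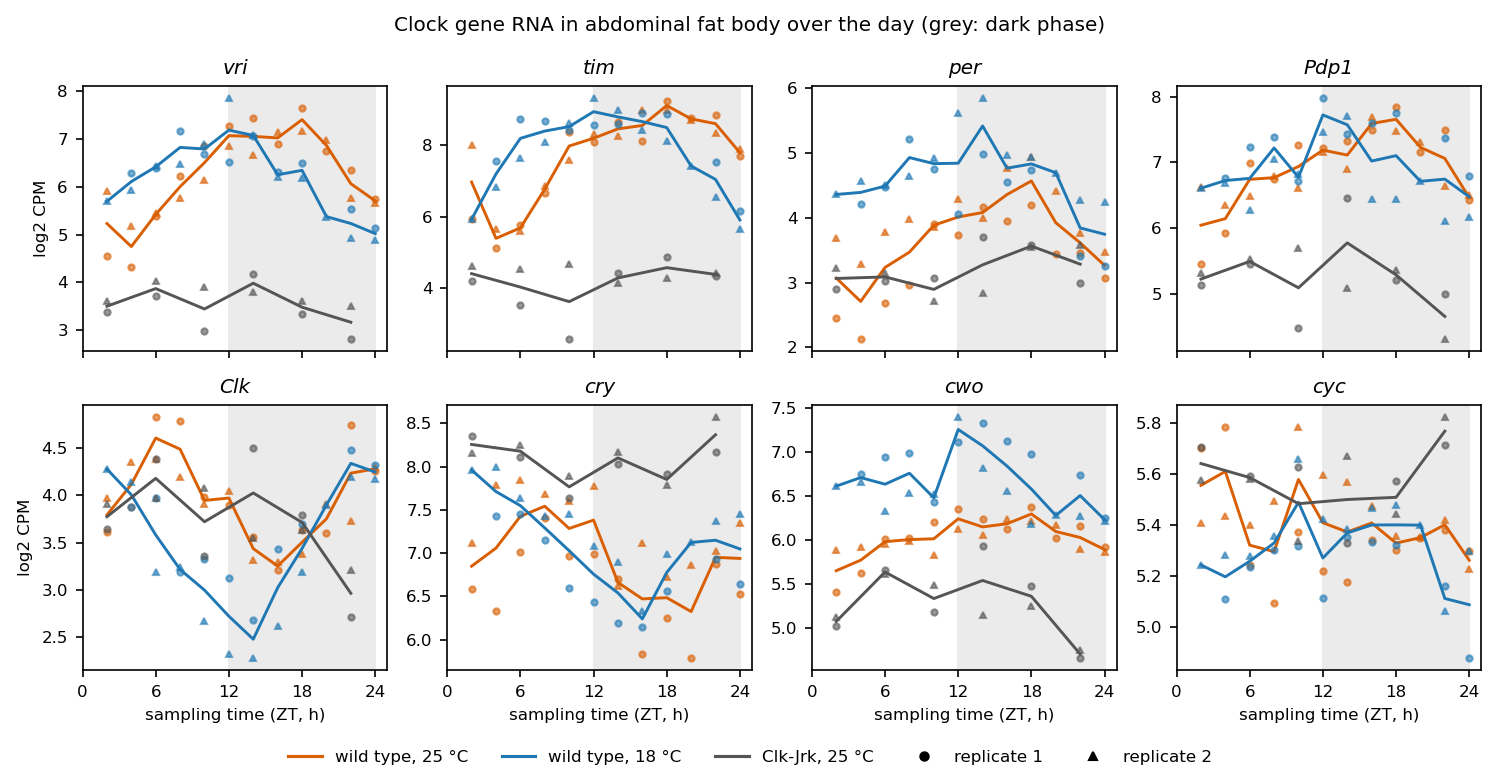
Levels of 8 core clock genes (vertical axis, log2 CPM) against sampling time (horizontal axis, ZT in hours, dark phase in grey) in wild type at 25 °C, wild type at 18 °C and Clk-Jrk at 25 °C, with libraries of replicate 1 as circles, those of replicate 2 as triangles, and lines through the means at each time. The tim and vri courses at 18 °C crest before those at 25 °C, with fitted peaks at ZT 12.6 and ZT 11.2 against ZT 17.3 and ZT 15.5, and both stay low in Clk-Jrk.

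The same question was asked of wild-type flies at 18 °C (n = 22 libraries). There tim RNA peaked at ZT 12.6 ± 0.47 h, 6.12-fold over its trough, and vri RNA at ZT 11.2 ± 0.44 h, 3.70-fold over its trough (edgeR adjusted p = 0.00167 and 0.000145). RNA of Clk (FBgn0023076) peaked at ZT 0.53 ± 0.40 h, 3.26-fold over its trough, and RNA of cry (FBgn0025680), the blue-light photoreceptor of the clock, at ZT 3.66 ± 0.68 h (adjusted p = 0.000123 and 0.00927). RNA of per peaked at ZT 12.4 ± 0.93 h, with an adjusted p of 0.0496. Endoplasmic reticulum, lipid and amino acid genes had members that peaked near or shortly after dawn.

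Of the 15 core clock genes, 5 passed over all genes and 9 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.000253). Among UDP-glycosyltransferases, 4 of 25 passed, both over all genes and when adjusted over the list alone (adjusted p = 0.0223). They were Ugt36D1, which peaked at ZT 3.68, Ugt36E1 at ZT 3.78, Ugt49C1 at ZT 2.77 and Ugt317A1 at ZT 5.38. Among genes of protein folding in the endoplasmic reticulum, 3 of 19 passed (9 when adjusted over the list alone). These were the lectin chaperones Calr and Cnx99A and the translocon subunit Sec61beta, which peaked at ZT 3.92, ZT 4.28 and ZT 3.87. Among genes of fatty acid synthesis and fat storage, 3 of 26 passed (7 when adjusted over the list alone). These were the acyl-CoA synthetase bgm, which peaked at ZT 24.0, the sugar sensor Mondo at ZT 1.68 and the diacylglycerol acyltransferase mdy at ZT 23.2. The share in neither list passed against other genes (adjusted p = 0.0614 and 0.111). Smaller counts passed among amino acid catabolism (hgo and Gs2, 2 of 25), cytochrome P450 enzymes (Cyp6a21 and Cyp6t1, 2 of 74), ovary markers (Cp15 and Vm26Ac, 2 of 28), antioxidant defence (Gclc, 1 of 21), immune recognition (PGRP-LB, 1 of 24) and glutathione S-transferases (GstZ2, 1 of 29). Large amplitudes were also seen in mib1 (1.12, peak at ZT 12.8), the lysine-degrading enzyme LKRSDH (1.05, ZT 1.45), CG7149 (1.04, ZT 3.02) and CG17560 (1.05, ZT 2.71).

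Over all genes, 193 of 9348 were rhythmic and 1423 had an unadjusted p under 0.05. Their median amplitude was 0.42, and 90 peaked between ZT 0 and ZT 6. The count was unstable: DESeq2 called 514, a term for replicate gave 567, replicate 2 alone gave 87, replicate 1 alone gave 0 (895 at an unadjusted p under 0.05), and 43 to 279 passed with a time point left out. Without a single library with photoreceptor RNA (replicate 1, ZT 24) 292 passed, and 43 with the term for the inferred step between incubators.

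Whether rhythms differed between the temperatures was tested directly, on the interaction of temperature with time. The clock genes vri, tim and Clk and the autophagy kinase gene Atg1 (FBgn0260945) had shifted courses, with earlier peaks at 18 °C. The peak at 18 °C minus that at 25 °C was −4.68 ± 0.66 h for tim, −4.36 ± 0.59 h for vri, −4.14 ± 0.95 h for Clk and −3.94 ± 0.78 h for Atg1 (adjusted p = 0.00216, 0.000453, 0.032 and 0.0138). The amplitudes of tim and vri differed by −0.21 ± 0.24 and −0.17 ± 0.16, within their errors, and those of Clk and Atg1 were higher at 18 °C by 0.40 ± 0.14 and 0.27 ± 0.09. Within replicate 1 tim, vri and Clk peaked −4.42, −4.10 and −4.63 h apart, and within replicate 2 −4.97, −4.81 and −3.89 h apart. The fitted shifts of per, Pdp1, cwo and cry were −3.20, −2.76, −3.06 and −3.55 h, and none of these differences passed.

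Of the 15 core clock genes, 3 differed over all genes and 5 when adjusted over the list alone, where nmo (adjusted p = 0.00292) and slmb (0.00847) joined the first 3 (Fisher's exact test, adjusted p = 1.53e-05). Not every shared rhythm moved. Of 13 genes rhythmic at both temperatures, where 0.764 would be expected of independent lists, 11 peaked earlier and 2 later at 18 °C, with a median of −2.83 h. Among them GstZ2 peaked at ZT 0.74 and Ugt36D1 at ZT 3.68 at 18 °C, against ZT 0.48 and ZT 3.37 at 25 °C (adjusted p = 0.897 for each difference). Other genes with a difference were Usp1, CtsL3, rost, CG9837 and Su(dx) (adjusted p = 0.0391 each), stx (0.0441) and pkm (0.0479). Their fitted peaks were further apart: the peak at 18 °C minus that at 25 °C was 10.2 ± 2.31 h for Usp1, 10.5 ± 1.69 h for CtsL3 and 10.3 ± 1.85 h for Su(dx). It was −8.92 ± 2.19 h for rost, −10.2 ± 1.43 h for CG9837, −11.1 ± 1.62 h for stx and −11.8 ± 4.89 h for pkm. At 25 °C these genes did not pass for rhythm (edgeR adjusted p from 0.111 for pkm to 0.604 for rost). CG9837 and pkm did not pass at 18 °C either (0.0866 and 0.179). Their fitted differences thus do not measure a shift of a rhythm shown at both temperatures. In all, 11 of 9348 genes differed, with 1303 at an unadjusted p under 0.05. Over 28 other fits vri and tim passed in 25 each, Atg1 in 18 and Clk in 14. The count was 46 in DESeq2, 5 in replicate 2 alone, 0 in replicate 1 alone (1139 at an unadjusted p under 0.05), 3 without the libraries with marker RNA of other tissues, 2 without ZT 4 or without ZT 6, and 0 with the inferred step between incubators and its interaction (752 at an unadjusted p under 0.05).

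The mean level over the day was then compared between 18 °C (n = 22) and 25 °C (n = 24) in wild type. Over all 9348 genes tested, 2178 were higher and 2354 lower at 18 °C (48.5% called), a background for the list counts below. At 18 °C some genes of lipid synthesis (9 of 26), immune signalling (10 of 24) and UDP-glycosyltransferases (12 of 25) held more RNA, and some of mitochondrial ribosomes (30 of 73) held less. As lists these passed with a preset correlation by camera and not with an estimated one (adjusted p = 0.917 each), and with marker means as covariates the median of lipid synthesis was −0.07. Desat1, the stearoyl-CoA desaturase that raises membrane fluidity, stood at 13.22 ± 0.31 at 18 °C and 12.43 ± 0.33 at 25 °C, a 1.73-fold rise seen at 12 of 12 times (log2 difference 0.79 ± 0.10, edgeR adjusted p = 1.19e-06). The clock genes per and cwo rose 1.90-fold and 1.59-fold, at 12 of 12 times each (adjusted p = 6.34e-05 and 3.16e-07), while Clk fell by 0.40 ± 0.10 on the log2 scale (adjusted p = 0.00235). The larval storage protein gene Lsp1beta (FBgn0002563) was lower at 12 of 12 times (log2 −3.25 ± 0.38, adjusted p = 5.58e-07). RNA of another tissue moved with temperature too: 26 of 28 ovary markers were lower at 18 °C, with a list median of −2.67.

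Among genes of fatty acid synthesis and fat storage, 9 of 26 rose and 1 fell, 16 did not pass, and 9 passed when adjusted over the list alone, 8 of them higher (camera adjusted p = 0.000516; adjusted p = 0.917 with an estimated correlation). The fatty acid elongase Baldspot rose 1.79-fold, the acyltransferase Agpat3 1.64-fold, the fatty acid transporter Fatp1 1.58-fold and Mondo 1.41-fold, each at 12 of 12 times. The list median was 0.20 in replicate 1 and 0.14 in replicate 2. Among genes of lipolysis and fatty acid oxidation, 7 of 22 rose and 1 fell, with the carnitine palmitoyltransferase whd 1.46-fold and the lipase Hsl 1.27-fold higher (camera adjusted p = 0.109). Its median was 0.22 in replicate 2 and −0.02 in replicate 1. Of 25 genes of sugar and glycogen metabolism, 8 rose and 17 did not pass, among the former the branching enzyme AGBE (2.33-fold), the trehalose transporter Tret1-1 (1.62-fold) and Ldh (1.80-fold) (camera adjusted p = 0.158). In both lists the counts adjusted over the list alone were the same. With the ovary, gut and muscle marker means of each library as covariates, the medians of fatty acid synthesis, lipolysis and sugar metabolism were −0.07, −0.04 and −0.25, below 0.

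Among genes of immune recognition and signalling, 10 of 24 rose and 14 did not pass, 9 when adjusted over the list alone (camera adjusted p = 0.0273; adjusted p = 0.917 with an estimated correlation). The NF-kappaB factors Rel and Dif rose 1.65-fold and 1.32-fold, and the recognition protein genes PGRP-LF and GNBP1 1.69-fold and 1.41-fold. The list median was 0.16 in replicate 1 and 0.24 in replicate 2, and the list no longer passed without replicate 2 (adjusted p = 0.177). Of 22 antimicrobial peptide genes, 7 rose and 1 fell, with BomS2 2.05-fold and Drsl5 2.44-fold higher, and the list showed no direction (median 0.05, mean −0.07, camera adjusted p = 0.392). Of 11 thermal acclimation markers, 6 rose and 2 fell, with TotA 2.60-fold and TotX 2.54-fold higher and Cyp4d20 lower (log2 −0.61) (camera adjusted p = 0.0828). The haemocyte markers, which belong to blood cells, rose beside these lists: 9 of 12 were higher, and their median was 0.99 in replicate 1 and 0.14 in replicate 2.

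Of 25 UDP-glycosyltransferase genes, 12 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.00909; adjusted p = 0.917 with an estimated correlation). Ugt36D1 rose 1.91-fold and Ugt37D1 2.19-fold, at 12 of 12 times each, and the list median was 0.61 in replicate 1 and 0.21 in replicate 2. The list no longer passed without replicate 1 (adjusted p = 0.101). Of 74 cytochrome P450 genes, 26 rose and 12 fell (28 and 12 when adjusted over the list alone, camera adjusted p = 0.0632), with Cyp4ac1 2.44-fold higher and Cyp4s3 lower (log2 −2.52). The P450 median was 0.35 in replicate 1 and 0 in replicate 2. Of 29 glutathione S-transferases 4 rose, with GstT1 1.46-fold higher, and 5 fell (camera adjusted p = 0.684). Of 21 antioxidant genes 4 rose and 5 fell, with the peroxiredoxins Prx2 and Prx3 lower (log2 −0.45 and −0.41) (median 0.03, camera direction down, adjusted p = 0.937).

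Of 73 mitochondrial ribosomal protein genes, 30 fell and 43 did not pass, 29 when adjusted over the list alone (camera adjusted p = 0.000453; adjusted p = 0.917 with an estimated correlation). The falls were small, with mRpL53 at −0.44 ± 0.06 and mRpL37 at −0.40 ± 0.06, each lower at 12 of 12 times. The list median was −0.31 in replicate 1 and −0.11 in replicate 2. Cytosolic ribosomal proteins (5 of 86 fell, 4 when adjusted over the list alone, RpS29 at −0.28, camera adjusted p = 0.272) and oxidative phosphorylation subunits (2 of 69 rose and 5 fell, camera adjusted p = 0.319) did not pass as lists. With a replicate term both passed, lower at 18 °C (adjusted p = 0.0177 and 0.00492), and they passed as well without replicate 2 (0.000597, cytosolic ribosomal proteins) or without replicate 1 (0.000105, oxidative phosphorylation). Of 32 proteasome subunits 5 rose (camera adjusted p = 0.208, and 0.0212 without replicate 1), of 19 genes of folding in the endoplasmic reticulum 5 rose and 1 fell, Ire1 1.38-fold higher (camera adjusted p = 0.501, median −0.16 in replicate 1 and 0.16 in replicate 2), and of 25 genes of amino acid catabolism 7 rose and 5 fell, P5cr-2 1.71-fold higher and hgo lower (log2 −0.44) (median 0.04, mean −0.02, camera adjusted p = 0.633). Of 21 genes of insulin, FoxO and fat body signals 8 rose and 1 fell, with the insulin-like peptide gene Ilp6 1.83-fold higher at 12 of 12 times (camera adjusted p = 0.0972).

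Of 12 genes of yolk, lipid carrier and storage proteins 2 rose and 2 fell. The ferritin subunit Fer1HCH rose 1.43-fold and the lipid carrier apolpp fell by 0.84 ± 0.17. The list passed without replicate 2 (lower, camera adjusted p = 0.000597). The yolk protein genes Yp1, Yp2 and Yp3 together took 7.31% ± 4.66 of counts at 18 °C and 12.8% ± 5.23 at 25 °C. That share was 2.70% and 8.18% in replicate 1 and 11.2% and 17.4% in replicate 2. Of 25 cytosolic and mitochondrial chaperones 2 rose and 4 fell, with Hsp27 and Hsp26 lower (log2 −1.83 and −1.48) (camera adjusted p = 0.272). Their mean difference was 0.56 in replicate 1 and −1.13 in replicate 2, so the chaperones had no common direction, and without replicate 1 the list passed as lower (camera adjusted p = 0.00124). Core clock genes counted 3 up and 1 down of 15, also when adjusted over the list alone (median −0.001, mean 0.08, camera adjusted p = 0.522).

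Marker RNA of other tissues differed between the temperatures and between replicates. The ovary list (camera adjusted p = 8.95e-07) had a median of −3.25 in replicate 1 and −1.29 in replicate 2, with the germline gene BicC at −1.68 and the vitelline membrane gene Vm32E at −5.18. Muscle markers were higher for 15 of 25 genes (camera adjusted p = 0.000516), with a median of 0.82 in replicate 1 and −0.03 in replicate 2. Haemocyte markers, such as eater at 2.51-fold (camera adjusted p = 0.00116), and neuron markers, 10 of 14 with Syt1 at 2.24-fold (camera adjusted p = 0.00532), were higher as well, and the neuron median was 0.94 in replicate 1 and 0.68 in replicate 2. For these 4 lists the adjusted p was 0.917 with an estimated correlation, and muscle and haemocyte markers no longer passed without replicate 1 (adjusted p = 0.81 and 0.319). Gut markers (1 of 23 higher, median −0.04, camera direction up), Malpighian tubule markers (2 of 12 lower), oenocyte and epidermis markers (3 higher and 3 lower of 12), spermatheca markers (2 tested, none called by edgeR) and mitochondrially encoded transcripts (12 tested, none called by edgeR) had camera adjusted p values of 0.84, 0.418, 0.271 and, for the last, 0.833.

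In all, 4532 of 9348 genes differed with temperature, 2178 higher and 2354 lower at 18 °C, of which 280 and 379 changed at least 2-fold. The test treated libraries as independent, but libraries of a replicate series shared deviations (median r 0.487 at 18 °C and 0.448 at 25 °C). A split of the same libraries by replicate number called 3985 genes in edgeR. The adjusted p values thus measure the spread between libraries, not that between series or collections. Genes changed at every time included CG7214 (6.19 ± 0.79), CG40485 (4.54 ± 0.34), Sgp (2.58 ± 0.30), the chemosensory gene Snmp1 (1.86 ± 0.15), yellow-c (1.86 ± 0.15), CG15553 (2.13 ± 0.15), phu (2.09 ± 0.30) and CG42269 (1.79 ± 0.22) among the higher. The lower ones included the oocyte histone gene BigH1 (−1.90 ± 0.36), mtrm (−1.84 ± 0.37), the piRNA pathway gene krimp (−1.79 ± 0.40), asp (−1.79 ± 0.35) and fzy (−1.74 ± 0.34). The count was 3928 without the libraries with marker RNA of other tissues, and 1085 with the ovary, gut and muscle marker means of each library as covariates.

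**Figure D2:**
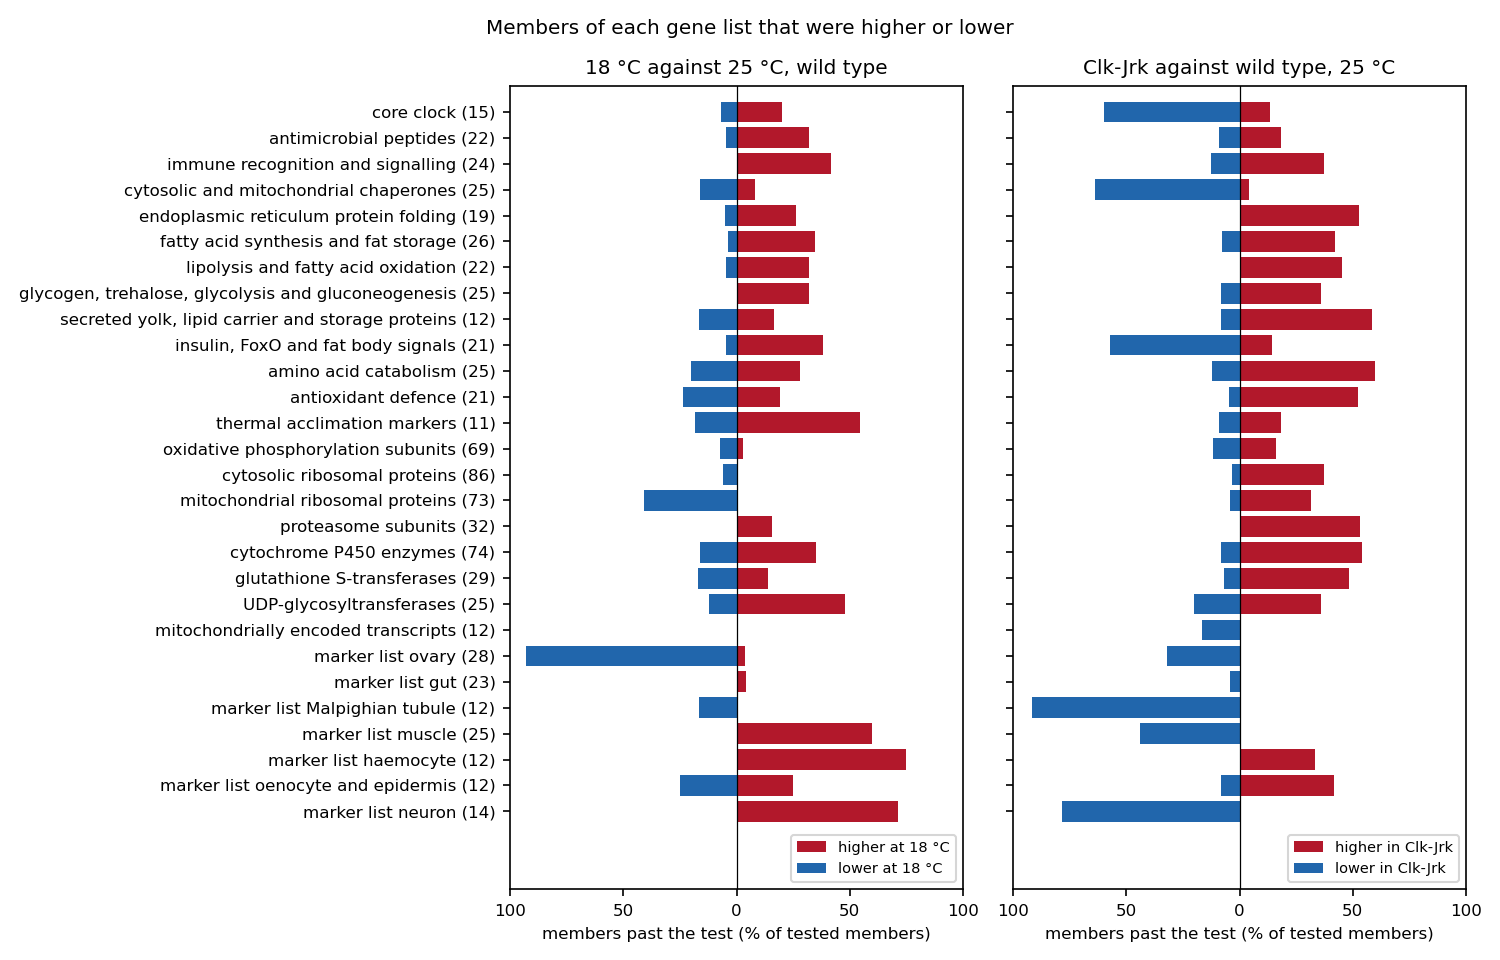
Share of the tested members of each gene list (horizontal axis, % of tested members, with the number tested in brackets) that were higher (red, to the right) or lower (blue, to the left) at 18 °C than at 25 °C in wild type and in Clk-Jrk than in wild type at 25 °C, by edgeR on scaled counts. The widest blue bars stand for ovary markers with temperature (26 of 28 lower) and for Malpighian tubule markers with genotype (11 of 12 lower).

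The next question was whether rhythms persisted in Clk-Jrk flies at 25 °C (n = 12 libraries), set beside the wild-type libraries at the same 6 times (n = 12). The large swings of tim and vri in wild type were not seen in Clk-Jrk. The tim amplitude was 0.38 ± 0.24 in Clk-Jrk against 1.51 ± 0.30 in wild type at the same times, and that of vri 0.26 ± 0.15 against 1.09 ± 0.19. The amplitude of per was 0.27 ± 0.12 against 0.67 ± 0.19, that of Pdp1 0.31 ± 0.23 against 0.56 ± 0.20 and that of cry 0.20 ± 0.08 against 0.41 ± 0.14. For cwo it was 0.36 ± 0.12 against 0.22 ± 0.07.

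With edgeR 0 genes passed in Clk-Jrk (1435 at an unadjusted p under 0.05, 231 in DESeq2, 0 with limma on TPM) and 0 in wild type at these 12 libraries (337, 22 and 0). In wild type vri and tim passed when adjusted over the core clock list alone (adjusted p = 0.00297 and 0.0217). The test of the difference in rhythm gave 0 genes with edgeR (908 at an unadjusted p under 0.05, 27 in DESeq2, 0 with limma on TPM), and vri alone passed when adjusted over the list alone (adjusted p = 0.0095, against 0.14 for tim). In Clk-Jrk 74 of 86 cytosolic ribosomal protein genes passed when adjusted over the list alone (78 at an unadjusted p under 0.05), against 0 in wild type at the same times (0 unadjusted as well), and 29 of 69 oxidative phosphorylation genes had an unadjusted p under 0.05. These genes move together and are not independent, and the Clk-Jrk mean of the cytosolic ribosomal list was highest at ZT 22 (10.62 and 10.68 in replicates 1 and 2). For the difference between genotypes 0 of the 86 passed by the list alone in edgeR (15 at an unadjusted p under 0.05). A test at these 12 libraries per genotype was sensitive to large swings only. Of simulated amplitudes of 1, 76% were recovered in wild type, and 67% for a difference set as a full loss of rhythm in Clk-Jrk. Simulated libraries were independent of each other, and these shares may be too high for the real ones. Over all genes even tim and vri did not pass in wild type at these times (edgeR adjusted p = 0.989 and 0.482).

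The mean level in Clk-Jrk was compared with that in wild type at the same 6 times. Clk RNA did not differ detectably, at 3.63 ± 0.51 in Clk-Jrk (n = 12) and 3.85 ± 0.50 in wild type (n = 12), a difference of −0.21 ± 0.15 (edgeR adjusted p = 0.249). The genes that CLK activates were lower: tim fell by 3.63 ± 0.27, vri by 2.78 ± 0.18, Pdp1 by 1.69 ± 0.20, cwo by 0.77 ± 0.09 and per by 0.61 ± 0.17 on the log2 scale, each at 6 of 6 times (adjusted p = 3.58e-07, 8.36e-08, 3.05e-05, 3.07e-05 and 0.0101). RNA of cry rose 2.14-fold at 6 of 6 times (adjusted p = 8.04e-06). Over all 9348 genes tested, 1735 were higher and 2328 lower in Clk-Jrk (43.5% called), a background for the list counts below. Beyond the clock, RNA was higher in Clk-Jrk for 40 of 74 cytochrome P450 genes, 15 of 25 genes of amino acid catabolism and 7 of 12 genes of yolk, carrier and storage proteins, and lower for 16 of 25 chaperones and for the insulin-like peptide Ilp6. As lists these 4 passed with a preset correlation by camera and not with an estimated one (adjusted p = 0.279, 0.279, 0.487 and 0.279).

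Of 15 core clock genes, 9 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.00043; adjusted p = 0.279 with an estimated correlation). Besides those named, the kinase genes nmo, sgg, dco and CkIIbeta fell by 1.37, 0.72, 0.52 and 0.41, and jet rose 1.32-fold. The list median was −0.37 in replicate 1 and −0.58 in replicate 2. Clk lies on chromosome 3L from 7763233 to 7775603 in the BDGP6.54 annotation.

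Of 74 cytochrome P450 genes, 40 rose and 6 fell (42 and 6 when adjusted over the list alone, camera adjusted p = 1.05e-13; adjusted p = 0.279 with an estimated correlation). Cyp6a8 rose 12.2-fold, from 7.29 ± 1.19 to 11.04 ± 0.32, Cyp309a2 23.2-fold, Cyp9h1 4.78-fold and Cyp4ac1 4.45-fold, each at 6 of 6 times. The P450 median was 0.34 in replicate 1 and 0.68 in replicate 2, and that of the next list 0.25 and 0.48. Of 29 glutathione S-transferases, 14 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 9.07e-06; adjusted p = 0.279 with an estimated correlation), with GstE3 3.64-fold and GstZ2 2.58-fold higher. Of 25 UDP-glycosyltransferases, 9 rose and 5 fell (median 0.20, mean −0.01, median −0.08 on TPM, camera adjusted p = 0.00043; adjusted p = 0.487 with an estimated correlation). Ugt302C1 rose 11.7-fold and Ugt35C1 3.17-fold. Of 21 antioxidant genes 11 rose and 1 fell (12 and 2 when adjusted over the list alone, camera adjusted p = 0.00363; adjusted p = 0.487 with an estimated correlation), with Gtpx 1.75-fold higher. The UDP-glycosyltransferases no longer passed without replicate 2 (adjusted p = 0.163), nor the antioxidant genes without replicate 1 (0.0523).

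Of 25 genes of amino acid catabolism, 15 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 5.54e-07; adjusted p = 0.279 with an estimated correlation). Gnmt and Sardh, which methylate glycine and demethylate sarcosine, rose 15.1-fold and 20.1-fold, and the aminotransferase Got1 2.26-fold. The wild-type SD of Gnmt was 2.51, and its difference was 6.86 in replicate 1 and 3.09 in replicate 2. The list median was 0.58 in replicate 1 and 0.40 in replicate 2. Of 26 genes of fatty acid synthesis and fat storage 11 rose and 2 fell (camera adjusted p = 0.00183, median −0.05 on TPM), with fabp 1.72-fold, ATPCL 1.74-fold and Dgat2 3.95-fold higher. Of 22 genes of lipolysis and fatty acid oxidation 10 rose, among them Acox57D-p (1.81-fold) (camera adjusted p = 0.000424). Of 19 genes of folding in the endoplasmic reticulum 10 rose, with Pdi 1.58-fold and ERp60 1.52-fold higher (camera adjusted p = 0.00043, median −0.03 on TPM). In these 3 lists the counts adjusted over the list alone were the same, and the adjusted p was 0.487 with an estimated correlation. Of 25 genes of sugar and glycogen metabolism 9 rose and 2 fell (10 and 2 when adjusted over the list alone, median −0.02 on TPM, camera adjusted p = 0.0131; adjusted p = 0.606 with an estimated correlation), with Gapdh2 higher by 0.58 on the log2 scale. This last list no longer passed without replicate 1 (adjusted p = 0.208).

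Of 12 genes of yolk, lipid carrier and storage proteins 7 rose and 1 fell (camera adjusted p = 0.00386; adjusted p = 0.487 with an estimated correlation). The larval storage protein genes Lsp2 and Lsp1beta rose 23.1-fold and 14.2-fold, the lipid transfer gene Mtp 1.76-fold and Yp1 1.79-fold. Yp1, Yp2 and Yp3 together took 17.4% ± 2.28 of Clk-Jrk counts. By replicate, the share was 16.2% in Clk-Jrk and 8.18% in wild type at 25 °C, over all 12 times, in replicate 1. In replicate 2 the shares were 18.6% and 17.4%, so most of the difference in share lay in replicate 1. Of 21 genes of insulin, FoxO and fat body signals, 12 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.487 with an estimated correlation). Ilp6 fell by 2.21 ± 0.15, the insulin receptor gene InR by 1.34 ± 0.23, foxo by 0.82 ± 0.11 and REPTOR by 1.10 ± 0.16, at 6 of 6 times each, while tobi, a glucosidase gene, rose 4.21-fold. This list no longer passed without replicate 1 (adjusted p = 0.0544).

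Of 25 cytosolic and mitochondrial chaperones, 16 fell and 1 rose (17 and 1 when adjusted over the list alone, camera adjusted p = 0.000237; adjusted p = 0.279 with an estimated correlation). Hsp70Ab fell by 3.45 ± 0.55, Hsp26 fell by 1.97 ± 0.29, Hsp22 fell by 2.11 ± 0.37 and Hsp68 fell by 1.20 ± 0.22 on the log2 scale, whereas Hsc70-4, the main constitutive member, differed by −0.08 ± 0.07. The list mean was 3.92 and 3.66 in the 2 replicates of Clk-Jrk. In those of wild type at 25 °C, over all 12 times, it was 4.98 and 5.19.

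Lists of general cell machinery rose by small amounts on scaled counts, and their medians lay below 0 on TPM. Of 86 cytosolic ribosomal proteins 32 rose and 3 fell (29 and 3 when adjusted over the list alone), of 73 mitochondrial ribosomal proteins 23 rose and 3 fell, and of 32 proteasome subunits 17 rose (21 when adjusted over the list alone), with RpS4, mRpL50 and Prosalpha6 at 1.45-fold, 1.55-fold and 1.38-fold (camera adjusted p = 0.000316, 0.00043 and 0.000237; adjusted p = 0.606, 0.606 and 0.487 with an estimated correlation). Their medians were 0.40, 0.36 and 0.19 in replicate 1 and 0.02, 0.05 and 0.25 in replicate 2. Of 69 oxidative phosphorylation subunits 11 rose and 8 fell (camera adjusted p = 0.0548, 0.0364 with a replicate term and 2.28e-05 without replicate 2, median −0.12 on TPM). Of 24 genes of immune recognition 9 rose and 3 fell, PGRP-LC 2.54-fold higher and PGRP-SD lower, log2 −1.17 (median −0.14 on TPM, camera adjusted p = 0.022; adjusted p = 0.487 with an estimated correlation). Of 22 antimicrobial peptide genes 4 rose and 2 fell (median −0.17, camera direction up, adjusted p = 0.471, and 0.0161 without replicate 1), and of 11 thermal acclimation markers 2 rose and 1 fell, smp-30 3.69-fold higher (camera adjusted p = 0.0288; adjusted p = 0.487 with an estimated correlation). Without replicate 1 the cytosolic and mitochondrial ribosomal proteins no longer passed (adjusted p = 0.977 and 0.391), nor did immune recognition and thermal acclimation without replicate 2 (0.434 and 0.228). These directions are relative to the bulk of genes. On TPM, which are not rescaled for a few abundant genes, the median of all genes was −0.28 against −0.08, and the medians of cytosolic ribosomal proteins, mitochondrial ribosomal proteins and proteasome subunits were −0.07, −0.10 and −0.09. Measured from the median of all genes on TPM, these 3 lists stood at 0.21, 0.18 and 0.19, and oxidative phosphorylation, immune recognition, fatty acid synthesis, folding in the endoplasmic reticulum, sugar metabolism and UDP-glycosyltransferases at 0.16, 0.14, 0.23, 0.25, 0.26 and 0.20.

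Marker RNA of other tissues was lower in Clk-Jrk for 11 of 12 Malpighian tubule genes, such as Uro at −1.95 and salt at −2.79 (camera adjusted p = 9.16e-07; adjusted p = 0.281 with an estimated correlation), 11 of 25 muscle genes (camera adjusted p = 0.0257), 11 of 14 neuron genes (camera adjusted p = 0.00433; measured from the median of all genes on TPM this list stood at 0.15) and 9 of 28 ovary genes (camera adjusted p = 0.168, and 0.03 without replicate 1). For muscle and neuron the adjusted p was 0.639 and 0.487 with an estimated correlation. The Malpighian median was −2.14 in replicate 1 and −0.91 in replicate 2. Malpighian and muscle markers no longer passed without replicate 1 (adjusted p = 0.0742 and 0.531), nor oenocyte and epidermis markers without replicate 2 (0.108). Haemocyte markers were higher for 4 of 12 genes (camera adjusted p = 0.079, and 0.0351 without replicate 1) and oenocyte and epidermis markers for 5, with 1 lower (camera adjusted p = 0.0286; adjusted p = 0.487 with an estimated correlation). Gut markers were lower for 1 of 23 (median −2.75, camera adjusted p = 0.176, and 0.000348 without replicate 2), with a median of −4.46 in replicate 1 and 0.80 in replicate 2. The spermatheca marker Hr39 was lower (log2 −0.65). Of 12 mitochondrially encoded transcripts, mt:ND6 fell by 5.63 and mt:ND4L fell by 2.53 on the log2 scale (camera adjusted p = 0.0639, and 6.31e-08 without replicate 2).

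In all, 4063 of 9348 genes differed between the genotypes, 1735 higher and 2328 lower in Clk-Jrk, of which 179 and 711 changed at least 2-fold. As with temperature, the adjusted p values measure the spread between libraries, not that between series or collections. Genes changed at every time included CG18417 (8.20 ± 0.44) and CG3348 (7.79 ± 0.47) among the higher, and Srg3 (−7.33 ± 0.26), hoka (−4.62 ± 0.27) and slow (−3.10 ± 0.20) among the lower. The count was 1338 to 2607 in 1 replicate alone and 2911 without the libraries with marker RNA of other tissues or low mitochondrial RNA. On TPM 12.1% of 5179 called genes were higher, against 42.7% on scaled counts.

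**Figure D3:**
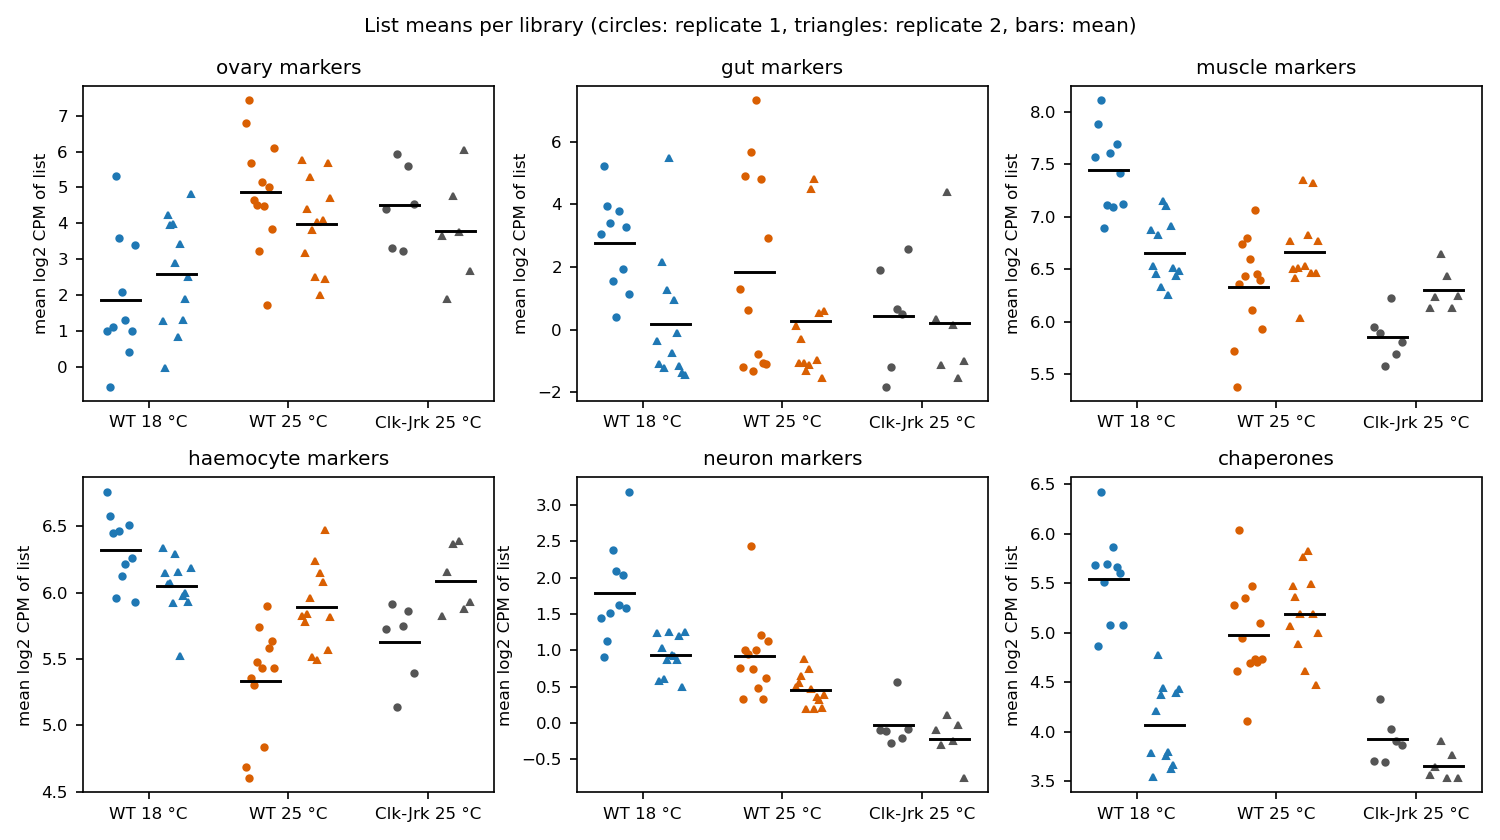
Mean level per library (vertical axis, log2 CPM of the list) of 5 marker lists of other tissues and of the chaperones in wild type at 18 °C, wild type at 25 °C and Clk-Jrk at 25 °C, with replicate 1 as circles, replicate 2 as triangles and bars at the mean of each replicate. The chaperone mean is 5.55 in replicate 1 and 4.07 in replicate 2 of wild type at 18 °C, and 3.92 and 3.66 in Clk-Jrk.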

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

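The tests that weigh explanations below, and the splits for the temperature levels, were chosen after the results were seen, and the splits within replicates were added after the other splits were seen, and so was the split count on the core clock list.

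The interaction of temperature with time passed for 11 genes, so that their course over the day differed between 18 °C and 25 °C. The adjusted p values were 0.000453 for vri, 0.00216 for tim, 0.0138 for Atg1, 0.032 for Clk, 0.0391 each for Usp1, CtsL3, rost, CG9837 and Su(dx), 0.0441 for stx and 0.0479 for pkm. Over 28 other fits the adjusted p ran from 1.02e-07 to 1 for vri, 2.1e-06 to 0.591 for tim, 0.000741 to 0.591 for Atg1 and 0.00239 to 1 for Clk. With libraries exchanged between the temperatures within each time, 6 of 40 splits, the real one included, gave as many as 11 genes, up to 21 in another split, so chance is not excluded for the count as a whole. With a replicate term in the fit and exchanges within a replicate, 13 genes passed and 1 of 40 splits reached that number (highest other 10). Within the core clock list, adjusted over the list alone, 5 genes passed and 1 of 40 splits reached that number (highest other 2). Exchanged libraries carry the difference in level with temperature as added spread, which can lower the counts of the other splits. These splits therefore cannot exclude chance for the differences in rhythm.

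Fitted peaks of the clock genes lay earlier at 18 °C, by a median of −3.55 h over per, tim, Clk, vri, Pdp1, cwo and cry, although the difference passed over all genes for tim, vri and Clk and not for the other 4. The fits that gave these peaks, 7 of 7 earlier, already left out the identical pair of columns, so the pair is not their source. That is how the peaks were found and not a separate test. The tables argue against mislabelled samples in 1 replicate series, since the smaller median shift of the replicates was −4.1 h (Pdp1 and cwo shifted by −0.01 and −0.95 h in replicate 1). A step between the day and the night incubator, inferred from the schedules, was put in the fit with its interaction. There 2 of the 7 genes, tim and Clk, kept a difference over the list alone (edgeR adjusted p = 0.0214 and 0.00211). Over all genes neither passed in that fit (edgeR adjusted p = 0.591 and 0.381). With 2 of the 7 passing, and over the list alone, the step is not excluded for tim and Clk. For vri (0.0722) and the rest of the 7 no difference passed, and the step and a shift cannot be told apart. Over all genes 0 passed in edgeR with the step (752 at an unadjusted p under 0.05). An earlier phase of the clock in the cold is a candidate explanation that stays open. The interaction tested the course of each RNA, not its phase apart from its amplitude.

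Germline and eggshell RNA was lower at 18 °C. Ovary tissue carried over in the dissection in differing amounts may account for it: the 355 genes at least 2-fold lower at 18 °C outside the ovary list followed the ovary list mean from library to library within a temperature, at a median r of 0.677 at 25 °C and 0.699 at 18 °C, against −0.037 and −0.044 for other genes (across genes, which are not independent replicates). With marker means as covariates 45 of the 355 still passed, against 174 of the 280 genes at least 2-fold higher. A higher share of fat body cells at 18 °C stays open, since less ovary RNA would raise the share of every remaining type together. The haemocyte list mean was higher by 0.561 (that list passed by camera and fry, but not without replicate 1, adjusted p = 0.319, whereas neuron markers passed without either, and with an estimated correlation the adjusted p was 0.917 for both). Not every other type fell with the ovary list, which does not settle the share of fat body cells. A change in ovaries or eggs with temperature stays open, as the ovaries were removed and were not analysed here.

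Chaperone RNA was lower in Clk-Jrk, at a list mean of −1.325 relative to wild type. Replicates of wild type at 18 °C differed by 1.478 in the same list mean, so the list can vary between series, but those libraries are not in this contrast. At 25 °C, over all 12 times, wild-type replicates differed by −0.213 (4.98 and 5.19), and both lay above those of Clk-Jrk (3.92 and 3.66). The contrast uses only the 6 shared times. At those times the lowest wild-type library stood at 4.474 (replicate 2, ZT 22) and the highest Clk-Jrk library at 4.335 (replicate 1, ZT 6). A stress of 1 wild-type series was thus not seen at 25 °C. A stress in handling or collection shared by both wild-type series stays open. Hsp70Ab stood at 6.44 ± 1.30 and 7.55 ± 0.86 log2 CPM in the replicates of wild type at 25 °C (n = 12 each) and at 4.35 ± 1.20 and 1.99 ± 1.89 in those of Clk-Jrk (n = 6 each). The tables argue against reads moving among the near-identical Hsp70 copies, because the 6 copies summed differed by −4.054 and 10 of the 19 other members were lower. Lower heat shock gene activity in the mutant stays open.

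Other splits of the samples gave these counts, out of 40 with the real one included. For levels with temperature 1 split reached 4532 genes (highest other 3), and for levels with genotype 1 split reached 4063 (highest other 2611), so random exchanges of libraries seldom reach either count. Libraries of a replicate series in wild type share deviations across times (median r 0.487 at 18 °C and 0.448 at 25 °C). These splits treat libraries as independent, so they cannot tell a group difference from 1 of its series or collections. A split by replicate number gave 3985 genes among the temperature libraries and 0 among the genotype libraries in edgeR (586 at an unadjusted p under 0.05, other tools not run), and within 1 replicate the temperature counts were 2966 and 3234. For rhythm at 25 °C, where times were reassigned among libraries, 1 split reached 37 (highest other 20), so reassigned times seldom reach that count. With a replicate term and times reassigned within a replicate, 3 splits reached 47 (highest other 929), so chance is not excluded in that fit. For rhythm at 18 °C 3 splits reached 193 (highest other 1858), and chance is not excluded. With the replicate term 1 split reached 567 (highest other 11), so times reassigned within a replicate seldom reach that count. On unadjusted counts, 5 splits reached 1435 in Clk-Jrk (highest other 2084), 25 reached 337 in wild type at the same times (highest other 2880) and 8 reached 908 for the difference between genotypes (highest other 2372), so chance is not excluded there. With the replicate term 3 splits reached 1435 in Clk-Jrk (highest other 2327), 23 reached 955 for the difference between genotypes (highest other 3911) and, on called genes, 7 reached 1 in wild type at the same times (highest other 3), so chance is not excluded in those fits either. The splits with several times the real count at 18 °C and in wild type at the same times point to a structure of the samples other than time. The split by replicate number among the temperature libraries shows that replicates differ, and whether they account for these splits was not tested apart from the way times were reassigned. Within the core clock list, adjusted over the list alone, 7 genes passed for rhythm at 25 °C and 9 at 18 °C. In each case 1 split reached the number (highest other 5 and 4), so reassigned times seldom reach those numbers.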

How the results depend on the processing

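The fits chosen after seeing the data were those on the identical pair, on 6 libraries left out, on a replicate term per group, on marker means as covariates, on the inferred incubator step with its interaction, and the list tests by replicate. The cause of each change below was not tested, except that a stricter adjusted p or a fold minimum cannot add calls by construction. For genes named in the comparisons of level, 3459 values for temperature and 2396 for genotype kept their direction and side of the threshold, 243 and 234 kept the direction and no longer passed, and 0 and 4 passed newly. For genes named in the rhythm tests, 547 values at 25 °C and 858 at 18 °C kept both, and 171 and 350 no longer passed. A direction turned in ND-AGGG with temperature (0.23 in the test chosen beforehand, −0.047 with marker covariates), in slmb with genotype (−0.27 on TPM), and for the genotype effect on expression level: Dro (0.43 without replicate 1, −5.04 without replicate 2).

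The temperature count of 4532 was 2966 to 3234 without a replicate, 4606 without ZT 20, 659 at a 2-fold minimum and 1085 with marker covariates (58.5% higher against 48.1%). The genotype count of 4063 was 1338 to 2607 without a replicate, 4125 without ZT 18, 2693 at an adjusted p under 0.01 and 890 at a 2-fold minimum. The 37 rhythmic genes at 25 °C became 103 in DESeq2, 75 without a filter, 3 to 12 without a replicate, 8 at an adjusted p under 0.01, 22 with a 12 h harmonic, 3 with the step, 20 without 4 of the 6 libraries, 16 with marker covariates, and 0 with ZT as a factor (393 at an unadjusted p under 0.05). Without a ZT, 16 (ZT 24) to 37 (ZT 6) passed, with 22 (ZT 4), 23 (ZT 16), 21 (ZT 18), 17 (ZT 20) and 20 (ZT 22) among them. The 193 at 18 °C became 514 in DESeq2, 567 with a replicate term (191 shared), 0 (895 at an unadjusted p under 0.05) to 87 without a replicate, 33 at an adjusted p under 0.01, 56 with the harmonic, 43 with the step, 292 without 1 of the 6 (replicate 1, ZT 24), 735 with marker covariates, and 0 with ZT as a factor (265 at an unadjusted p under 0.05). Without a ZT, 43 (ZT 16) to 279 (ZT 24) passed, with 111 (ZT 2), 86 (ZT 4), 62 (ZT 6), 101 (ZT 8), 120 (ZT 12), 54 (ZT 14), 103 (ZT 20) and 95 (ZT 22) among them.

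The 11 differences in rhythm between temperatures became 46 in DESeq2, 51 without a filter, 7 on TPM, 0 (1139 at an unadjusted p under 0.05) to 5 without a replicate, 2 at an adjusted p under 0.01, 6 with both identical columns kept, 3 with that pair as ZT 2, 3 without 5 of the 6 libraries, 27 with marker covariates, 0 with ZT as a factor (176 at an unadjusted p under 0.05) and 0 with the step and its interaction (752). Without a ZT, 2 (ZT 4, ZT 6) to 12 (ZT 14) passed, with 4 (ZT 2, ZT 18, ZT 20), 6 (ZT 8, ZT 10, ZT 24), 3 (ZT 16) and 5 (ZT 22) among them. The counts of 0 in edgeR became 231 (DESeq2), 2 (without ZT 6) and 2 (ZT as a factor) in Clk-Jrk, and 22 (DESeq2), 1 (no filter) and 1 (replicate term) in wild type at the same times. For the difference between genotypes they became 27 (DESeq2), 1 (no filter), 3 (without replicate 2), 1 (without ZT 6), 3 (without ZT 14), 1 (all 24 wild-type libraries) and 5 (marker covariates). With an estimated correlation 0 lists passed, against 8 with temperature and 22 with genotype at the preset correlation by camera (10 and 20 by fry). In wild type the replicate numbers marked a difference shared in part by both temperatures. Deviations from the mean of each time correlated at a median of 0.37 (−0.152 to 0.678) between libraries of the same ZT and replicate at 18 °C and 25 °C, over 0.1 in 8 of 10. Over all 120 pairs of times the median was 0.335. Between genotypes 1 of 6 was over 0.1 (median −0.22), so no shared difference was seen there. Samples were not paired, and the main fits held no replicate term. With a replicate term the temperature and genotype counts were 5539 and 4210.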

Other observations

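The hypothesis on the region near Clk and its first test were written after the changed genes were seen, and the test of the same region with temperature was written before its result.

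Replicates differed from each other as series in wild type. Mitochondrially encoded genes took 6.52% of counts in replicate 1 and 2.56% in replicate 2 at 18 °C (ranges 4.49% to 8.97% and 2.36% to 3.15%), and 5.68% and 2.33% at 25 °C. Yp1, Yp2 and Yp3 together took 2.70% and 11.2% at 18 °C and 8.18% and 17.4% at 25 °C. Heat shock genes parted the replicates at 18 °C: Hsp70Ab stood at 8.57 ± 0.74 log2 CPM in replicate 1 (n = 10) and 5.56 ± 1.46 in replicate 2 (n = 12), Hsp22 at 3.71 ± 0.93 and 0.89 ± 0.56, and the co-chaperone gene stv at 7.09 ± 0.51 and 5.83 ± 0.44. These replicate differences were not tested.

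RNA of photoreceptor cells was high in a pair of libraries. The rhodopsin gene ninaE reached 802.8 CPM and the arrestin gene Arr2 346.2 CPM in wild type at 25 °C, replicate 1, at ZT 10, and 534.0 and 306.7 CPM in wild type at 18 °C, replicate 1, at ZT 24, against medians of 0.61 and −0.43 log2 CPM at 25 °C and 1.84 and 0.69 at 18 °C. In Clk-Jrk ninaE reached 20.7 CPM at most. The trypsin gene alphaTry, from the gut, reached 1730.6 CPM at 25 °C and 1324.2 CPM at 18 °C.

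Some large genotype differences lie near Clk, which raised the hypothesis that a chromosome segment carried along with the mutant allele may hold other strain variants. Genes changed at least 4-fold near Clk included CG18417 at 0.363 Mb (8.20), CG8539 at 0.266 Mb (3.33), Srg3 at 1.68 Mb (−7.33), hoka at 2.86 Mb (−4.62) and slow at 3.38 Mb (−3.10). Within 5 Mb of Clk the share of genes changed at least 4-fold was 1.42 times that elsewhere (24 of 772 genes against 188 of 8560, odds ratio 1.43, 95% interval 0.887 to 2.21, Fisher's exact test p = 0.102), so an excess was not shown. Within 1 Mb, CG18417 and CG8539 were the 2 changed genes of 171 (1.17%, against 2.20% outside 5 Mb), so the share nearest to Clk was not raised, and 1477 of 7986 overlapping windows of the same size elsewhere held as high a share as that around Clk (3.11%). With temperature the same ratio was 1.1 (odds ratio interval 0.484 to 2.19), so that a property of the region and a segment cannot be told apart at these counts.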
